A study of Ammopiptanthus mongolicus with 6 samples.

How the data were processed

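Leaf mesophyll RNA of wild-type Ammopiptanthus mongolicus was extracted with Trizol and made into Illumina TruSeq libraries, per the labels' protocols. The 6 libraries are an untreated control, drought at 1, 24 and 72 h, and cold at 1 and 72 h, assigned from the treatment and time in the labels. The series' design text speaks of triplicates, while each treatment and time analysed here is 1 sample, so nothing was averaged and the spread between plants could not be estimated. How drought and cold were applied, and whether the control was sampled at the time of day of the stress libraries, is not given in the sources used here.

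The authors deposited 1 table per library with the count of uniquely assigned reads per unigene, per the file headers. Bowtie 0.12.2 is named in the submitters' processing notes. The assembler, the reads assembled and any filter on unigenes are not given in the sources used here. Each header states the total of the library, and the counts summed to exactly that total. The tables list only unigenes with at least 1 read, so a unigene missing from a table was taken as 0 reads. The deposited RPKM equalled the count per kilobase of unigene scaled by that total, with a largest relative deviation of 8.68e-09. The deposited percent coverage is the share of a unigene's length under reads, per the file headers. A unigene with 1 read was covered over 49 bases in every library. The files pair no identifier with a gene name, no genome was used, and the 23 gene lists fixed by annotation keyword, cell type markers included, could not be applied. Of the 67955 unigenes, 19756 are contigs of 8958 clusters by their identifiers. Contigs of 1 cluster can be near-identical copies or splice forms that compete for uniquely assigned reads, so their single values are uncertain. Whether counting used strand is not given in the sources used here.

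For each comparison of 2 libraries the ratio of reads over library totals was taken with its exact 95% interval (Clopper-Pearson, conditional on the sum of both counts, with scipy 1.17.1). A unigene was called higher when the interval lay above 2 and lower when it lay below the inverse of 2. Against 0 reads this needed at least 9 or 10 reads, depending on the comparison, so unigenes near the median of 8 to 10 reads per detected unigene could seldom be called. Where a library had 0 reads, folds are ratios to a floor of 3 counts in that library, which is 0.642 to 0.698 CPM. The count of the other library was taken as observed. The lower 95% bound of the exact interval is therefore smaller, and it is given beside these folds. The intervals cover counting error only, and the floor allows for that of the 0 count only. This is a fixed rule of size and not a test across samples, because a model with 1 library per group has no replicate error. The comparisons were each stress library against the control, cold against drought at 1 and at 72 h, and 4 steps in time within a stress. The unigenes named are the 2 higher and the 2 lower with the firmest interval bound in each of the first 7 comparisons. The grouping, this rule, the main settings and the alternatives not marked otherwise were fixed before the data were examined.

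The rule was tested on simulated data, with Poisson counts drawn from the pooled rates of each pair of libraries and 200 unigenes with at least 40 reads in the pair changed by a known fold. Over 33 simulations the intervals held the true fold for 96.2% of changed unigenes, and for 92.5% in the lowest. These draws hold counting error only, for which the interval is built. They check the computation and not the spread between plants. Over 11 comparisons of 67955 unigenes, 84 to 91.5% of 4-fold changes and 99.5 to 100% of 8-fold changes were called, no 1.5-fold change was called, and 3 to 14 unchanged unigenes were called per simulation. Unchanged libraries against a shared control were simulated 20 times per setting, without and with an assumed coefficient of variation between plants.

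Alternatives were TMM and upper-quartile factors (edgeR 4.0.16) and median-of-ratios size factors (DESeq2 1.42.0), at least 10 reads, a 99.9% interval, a bound of 1 or 4 in place of 2, an assumed coefficient of variation of 0.2 or 0.4, the deposited RPKM with 1 added and a ratio of at least 2 where the larger RPKM was at least 5, and unigenes of at least 500 bases. Libraries were also compared by correlation of log2(RPKM + 1). Totals without the 100 most abundant unigenes, and all libraries thinned to about 2150015 reads each, were added after seeing the data. R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.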

Results

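Leaf RNA of Ammopiptanthus mongolicus, an evergreen broad-leaved shrub of the Central Asian desert, was sequenced from untreated plants and from plants under drought or cold. The design addresses how the leaf transcriptome differs with each stress and with its duration. There were 6 libraries, 1 untreated control, 3 of drought taken at 1, 24 and 72 h and 2 of cold taken at 1 and 72 h. The control held 4673249 uniquely assigned reads. The drought libraries held 4305590 reads at 1 h, 4300030 at 24 h and 4639933 at 72 h, and the cold libraries held 4511083 at 1 h and 4301593 at 72 h. Reads fell on 67955 assembled transcripts (unigenes) of 200 to 14618 bases, and 46866 of these were detected in all 6 libraries. Detected unigenes numbered 59618 in the control, 59714, 58539 and 59262 in drought at 1, 24 and 72 h, 60009 in cold at 1 h and 56933 in cold at 72 h. Unigenes carry assembly identifiers and no gene names in the files, so they are reported by identifier and grouped by their behaviour over stress and time, not by function.

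Each treatment and time had 1 library, so no difference below has a replicate check and no p-value across samples was computed. A unigene was called higher or lower when the whole 95% counting interval of its ratio between 2 libraries lay beyond 2-fold. These intervals cover counting error only. They compare the libraries and not the conditions, and reads without molecular identifiers are not independent molecules. With 6 unchanged libraries simulated from the pooled counts, 10.3 unigenes per comparison with the control passed by counting error, and at most 19. An assumed coefficient of variation between plants of 0.2 raised that mean to 88.9, and one of 0.4 raised it to 2139, above every count in the comparisons without cold 72 h. The observed spread among unigenes with at least 1000 reads in a pair of libraries corresponded to 0.094 to 0.193 for the pairs without the cold 72 h library, treatment differences included, and to 0.260 to 0.315 for the pairs with it. The spread of less abundant unigenes between plants is unknown.

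The cold 72 h library stood apart from the 5 others. Its Pearson correlation of log2(RPKM + 1) across unigenes was 0.81 to 0.83 with each of them, and the other 10 pairs lay between 0.91 and 0.93. Unigenes are not independent replicates, and these values only describe the libraries. The closest pair by the number of called unigenes was drought 72 h and cold 1 h, with 213, followed by drought 24 h and drought 72 h, with 214. Cold 72 h was higher than all 5 other libraries at 1118 unigenes and lower than all 5 at 558. The next highest such total was 28 for the control, followed by 22 for drought 24 h and 18 for drought 1 h.

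**Figure D1:**
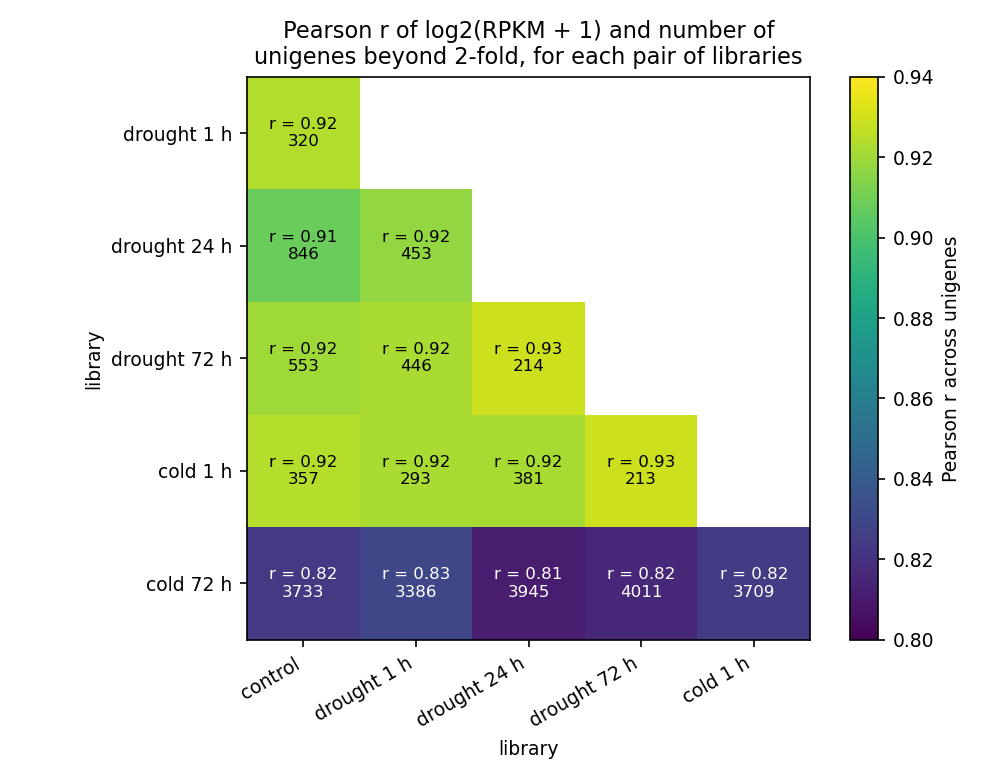
Pearson r of log2(RPKM + 1) across unigenes (colour and upper value) and the number of unigenes beyond 2-fold (lower value) for each of the 15 pairs of libraries. The 5 pairs with cold 72 h have 3386 to 4011 unigenes, and the other 10 pairs have 213 to 846.

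Drought was compared with the control at 3 times. At 1 h, 215 unigenes were higher and 105 lower. At 24 h, 443 were higher and 403 lower, and at 72 h, 252 were higher and 301 lower. The 24 h split turned to 2141 and 2202 with the interval only required to exclude 1 and a ratio of at least 2. It was 2525 and 2792 with the ratio of RPKM + 1, so its direction depends on the setting. The median fold among higher unigenes was 5.43 at 1 h, 5.27 at 24 h and 4.46 at 72 h with 0.5 added to counts. With counts under 3 set to 3 it was 4.65, 4.71 and 4.18. The higher set of 24 h took 3.83% of the reads of that library and 1.18% of the control's. The lower set of 24 h took 1.22% against 4.44% in the control.

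Unigene36437_All (776 bases) had 62.5 RPKM against 2.48 in the control, a ratio of 25.2 (95% interval 13.02 to 55.9), and stood at 11.7 RPKM at 24 h and 7.499 at 72 h. Unigene37259_All (761 bases) had 63 reads against 2, a ratio of 34.2 (9.08 to 288.5), with 43 and 34 reads at the later times. In cold it had 23 reads at 1 h and 2 at 72 h. Unigene21573_All (285 bases) had 84 reads in the control and 0 in every drought library. Against a floor of 3 counts it was 25.8-fold lower at 1 h (lower 95% bound 20.5) and 27.8-fold lower at 72 h (22.1). Unigene12559_All (418 bases) was 18.5-fold lower at 1 h (9.55 to 41.2), from 92.7 to 5.001 RPKM.

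At 24 h the leading higher unigene was Unigene35165_All (3231 bases), at 240 RPKM (232 to 248) against 11.3 in the control (9.63 to 13.1), a ratio of 21.3 with a lower 95% bound of 18.25. It was also above the control at 1 h, with 120 RPKM, and at 72 h, with 72.6 RPKM. In cold it stood at 34.4 RPKM at 1 h and 42.95 RPKM at 72 h, also above the control. Its reads covered only 27.6 to 28.0% of its length in every library, so its RPKM averages over bases without reads. CL6604.Contig2_All (2548 bases) had 0 reads in the control and in drought at 1 h, 61 reads at 24 h and 158 at 72 h. Against the floor it was 22.1-fold (lower 95% bound 17.4) and 53.0-fold (42.6) above the control. In cold it had 32 reads at 1 h and 10 at 72 h. Unigene8039_All (855 bases) had 36 reads at 72 h and 0 in the control, 12.1-fold higher against the floor (lower 95% bound 9.33). It had 10 reads at 1 h and was not listed at 24 h, taken as 0 reads. CL7853.Contig4_All (718 bases) had 92 control reads and 0 at 24 h, 28.2-fold lower against the floor (lower 95% bound 22.5). In cold it had 14 reads at 1 h and 22 at 72 h. Unigene55273_All (741 bases) had 46 control reads and 0 at 72 h, 15.2-fold lower against the floor (lower 95% bound 11.9). In cold it had 3 reads at 1 h and 0 at 72 h.

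Most drought differences were called at 1 time only. Of the 676 unigenes higher at any time, 113 were called at 1 h only, 274 at 24 h only and 98 at 72 h only, 89 at 24 and 72 h, and 43 at all 3 times. Of the 590 lower at any time, 45 were called at 1 h only, 232 at 24 h only and 138 at 72 h only, 115 at 24 and 72 h, and 44 at all 3 times. Among these, 5 unigenes were higher at one time and lower at another, named here after their values were seen. CL566.Contig1_All was lower at 1 h and higher at 24 and 72 h, and CL7200.Contig2_All, Unigene1148_All, Unigene15180_All and Unigene494_All were higher at 1 h and lower at 72 h. Drought 1 h and 24 h shared 80 higher and 56 lower unigenes, and independent lists of those sizes would share 1.54 and 0.683. Such expected numbers, here and below, count every unigene with a read in both comparisons, 61968 for this pair. Unigenes with few reads can seldom be called, so these expected numbers are too low. Drought 24 h and 72 h shared 132 higher and 159 lower unigenes, where independent lists would share 1.805 and 1.961. All comparisons share the 1 control, which could not be split, so part of this excess may come from it. In the simulation of unchanged libraries 0.1 unigenes were called in the same direction at all 3 times with counting error alone, 1.7 with an assumed coefficient of variation of 0.2 and 196.6 with one of 0.4, against 87 observed. A call missed at one time does not show that the unigene differs between times. Compared directly, drought 24 h against drought 1 h gave 145 higher and 308 lower unigenes, drought 72 h against 24 h gave 103 and 111, and drought 72 h against 1 h gave 96 and 350. With an assumed coefficient of variation of 0.4 the counts against the control became 30 at 1 h, 120 at 24 h and 70 at 72 h.

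**Figure D2:**
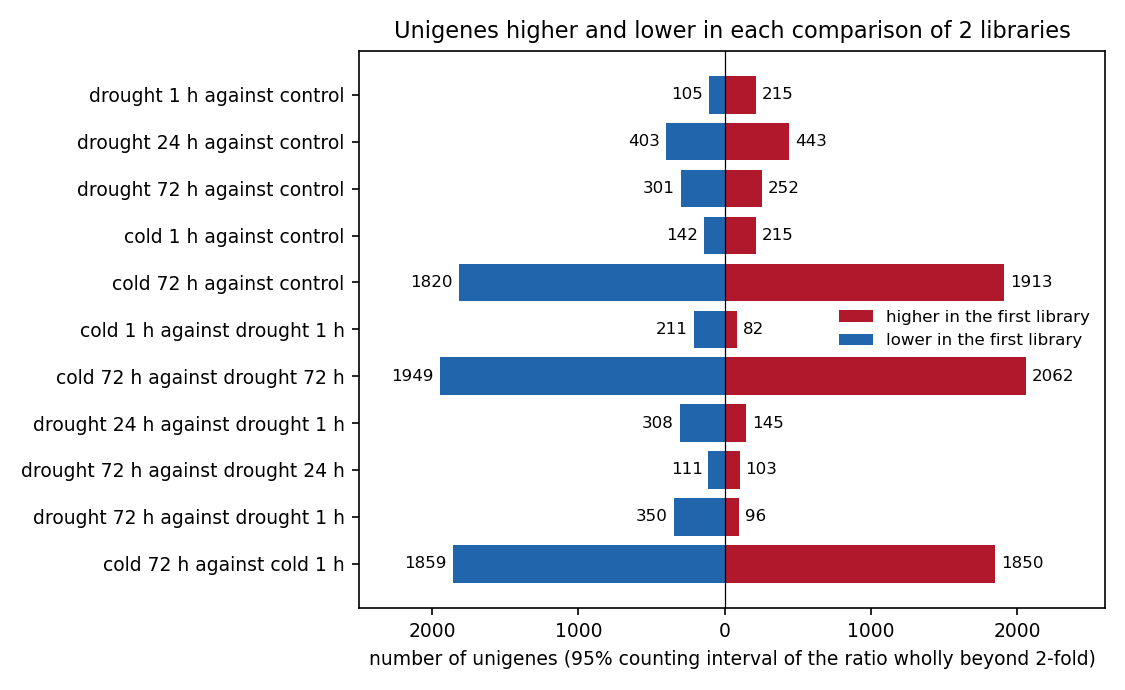
Number of unigenes higher (right) and lower (left) in the first library of each comparison, by the 95% counting interval lying wholly beyond 2-fold. The 3 comparisons with cold 72 h have 1820 to 2062 unigenes in each direction, and every other bar has at most 443.

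Cold for 1 h was compared with the same control. Here 215 unigenes were higher and 142 lower, with median folds of 5.02 and 4.20 with 0.5 added to counts, or 4.36 and 3.86 with counts under 3 set to 3. Under trimmed-mean (TMM) scaling the split became 164 higher and 178 lower, so the excess of higher unigenes depends on the scaling. Unigene12057_All (617 bases) had 62 reads against 0 in the control, at least 21.4-fold higher, and had 1 read at 72 h of cold. In drought it had 14, 6 and 13 reads at 1, 24 and 72 h. Unigene38706_All (622 bases) had 90 reads against 2, a ratio of 46.6 (12.5 to 390.8), and kept 68 reads at 72 h. Its drought reads were 13, 5 and 15 at 1, 24 and 72 h. Unigene12559_All, also lower in drought, was 24.96-fold lower (11.9 to 63.0). CL2614.Contig3_All (277 bases) was 23.3-fold lower (10.5 to 64.6), from 112 to 4.80 RPKM. It was low in drought too, with 145 reads in the control and 9, 4 and 20 in drought at 1, 24 and 72 h.

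Cold for 72 h gave the most called unigenes of the 5 comparisons with the control, 1913 higher and 1820 lower. The higher set took 16.1% of the reads of the cold library against 2.70% of the control's, and the lower set took 2.78% against 9.43%. Among unigenes with at least 100 reads in the 2 libraries together, 13.4% were called, against 1.08 to 3.31% in the other 4 comparisons. With counts under 3 set to 3, 312 unigenes were at least 16-fold higher and 32 at least 16-fold lower. With library totals as the scale, the median log2 ratio of the 29000 unigenes with at least 20 reads was -0.23. It was 0.05 with TMM, 0.08 with median-of-ratios and -0.03 with upper-quartile factors, so this shift depends on the scaling. TMM scaling gave 2502 higher and 1084 lower, whereas an interval only required to exclude 1 with a ratio of at least 2 gave 4051 higher and 7009 lower, and unigenes of at least 500 bases gave 987 higher and 1088 lower.

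Unigene16277_All (405 bases) had 573 reads, 329 RPKM, against 0 in the control and 2 to 6 in the other libraries. Against the floor it was 207.5-fold higher than the control (lower 95% bound 168.2). CL3732.Contig1_All (1436 bases) had 3.43 RPKM in the control (95% Poisson interval 2.17 to 5.14), 35.7 at 1 h of cold (31.2 to 40.6) and 664 at 72 h (644 to 684), a ratio of 194 (129 to 306) at 72 h. Its drought values were 2.10, 2.27 and 4.95 RPKM at 1, 24 and 72 h. Unigene21573_All had 0 reads against 84, 25.8-fold lower against the floor with library totals and 21.2-fold under TMM scaling. The 95% interval of the ratio, with library totals, began at 20.5-fold lower. Unigene5181_All (310 bases) was 37.9-fold lower (15.99 to 118), from 142 to 3.75 RPKM, and lay at 4.501 to 21.0 RPKM in drought.

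The overlap of the 2 cold times was small beside the 72 h sets. Of the 215 unigenes higher at 1 h, 57 were also higher at 72 h and 3 were lower, CL4346.Contig4_All, Unigene36220_All and Unigene36547_All, named here after their values were seen. Of the 142 lower at 1 h, 51 were also lower at 72 h and 10 were higher. For these opposite calls no number expected of independent lists was computed. Independent lists would share 6.65 and 4.18. The simulation of unchanged libraries gave 0.6 with counting error alone, 5.7 with a coefficient of variation of 0.2 and 487 with one of 0.4, against 108 observed in both directions together. Of the higher unigenes of drought 1, 24 and 72 h, 31.6, 20.8 and 25.8% were also higher at cold 72 h, against 26.5% for cold 1 h. For lower unigenes the shares were 43.8, 36.2 and 32.9%, against 35.9%. The overlap was therefore not particular to cold, and all of these shares rest on the same control. The split of 57 and 51 became 480 and 534 with an interval beyond 1 and a ratio of at least 2. It became 551 and 881 with the ratio of RPKM + 1. Directly, cold 72 h against cold 1 h gave 1850 higher and 1859 lower unigenes. The split was 2485 and 948 under TMM scaling, and 3639 and 7697 with the interval only required to exclude 1 and a ratio of at least 2.

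Cold and drought were compared at matched times, which does not involve the control. At 1 h, 82 unigenes were higher in cold and 211 lower. With the interval only required to exclude 1 and a ratio of at least 2, the numbers were 1313 and 1343, so the excess of lower unigenes was nearly absent under that bound. With the ratio of RPKM + 1 the numbers were 1981 and 1908, an excess of higher unigenes. Unigene21163_All (364 bases) had 77 reads in cold and 1 in drought, a ratio of 73.5 (12.8 to 2940), and 681 reads at 72 h of cold. CL566.Contig1_All (791 bases) had 40 reads against 0, at least 12.7-fold higher in cold. Unigene36437_All was 73.0-fold lower in cold (24.6 to 357), and Unigene5669_All (311 bases) was 22.3-fold lower (8.38 to 83.6). Unigene5669_All was also low in later drought, with 56 reads in the control and 85, 7 and 12 in drought at 1, 24 and 72 h. In cold it had 4 reads at 1 h and 20 at 72 h.

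At 72 h, 2062 unigenes were higher in cold and 1949 lower. The split was 2578 and 1193 under TMM scaling, and 4054 and 7023 with the interval only required to exclude 1 and a ratio of at least 2. Unigene678_All (353 bases) had 981 reads in cold and 1 in drought, a ratio of 1058 (190 to 41837). Unigene88_All (575 bases) stood at 885 RPKM against 2.999, a ratio of 295 (150 to 684). CL8238.Contig1_All (1105 bases) was 59.0-fold lower in cold (36.2 to 104). Its level was 35.4 RPKM in the control and 168, 415 and 199 RPKM in drought at 1, 24 and 72 h. In cold it was 56.8 RPKM at 1 h and 3.37 RPKM at 72 h. Its reads covered 52.5 to 53.3% of its length in the control and drought libraries. CL7767.Contig1_All (760 bases) had 1 read in cold and 122 in drought, 113-fold lower (19.9 to 4504).

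**Figure D3:**
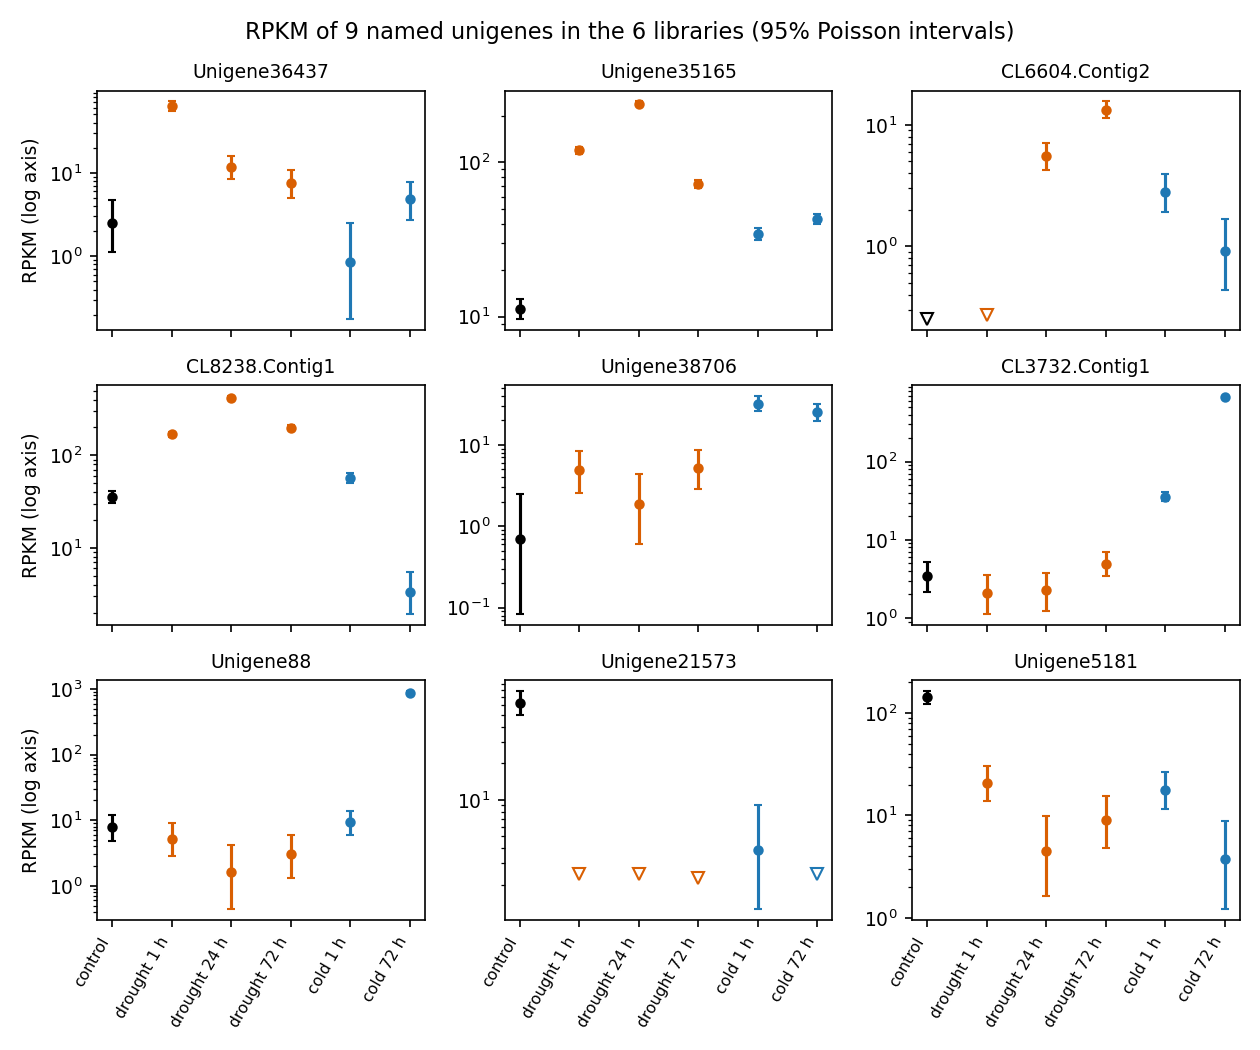
RPKM (log axis) of 9 named unigenes in the control (black), drought (orange) and cold (blue) libraries, with 95% Poisson intervals; open triangles mark 0 reads and are drawn at the level of 3 reads. CL3732.Contig1 reaches 664 RPKM at 72 h of cold, and CL8238.Contig1 is highest at 24 h of drought, at 415 RPKM, and lowest at 72 h of cold, at 3.37 RPKM.

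The 2 stresses shared unigenes in their comparisons with the control. At 1 h, 36 were higher and 27 lower in both drought and cold. The split turned to 11 and 16 at the stricter confidence level, 1 and 6 beyond 4-fold and 2 and 6 with an assumed coefficient of variation of 0.4. Independent lists would share 0.744 and 0.240 and the simulation of unchanged libraries, in both directions together, gave 0.7 with counting error alone, 7.1 with a coefficient of variation of 0.2 and 484 with one of 0.4. At 72 h, 65 were higher and 99 lower in both, where independent lists would share 7.81 and 8.87 and the simulation gave 0.35, 5.7 and 481 at the same settings, against 164 observed. TMM scaling turned the 72 h split into 72 and 73. Sharing was not confined to matched times. Cold 1 h shared 80 higher and 75 lower unigenes with drought 24 h, and 78 higher and 78 lower with drought 72 h. In all 5 stress libraries 15 unigenes were higher and 13 lower than in the control. They are the 28 unigenes at which the control lay apart from all 5 others, beside 22 for drought 24 h and 18 for drought 1 h. A set common to both stresses cannot be told apart here from a difference of the control itself. All overlaps above rest on the same control library, whose time of day at sampling, relative to the stress libraries, is not given in the sources used here.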

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

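At the same time point, some unigenes lay beyond 2-fold of the control in opposite directions under the 2 stresses, and with 1 library each the difference was not tested across samples. At 1 h there were 2 such unigenes, named here after their values were seen. CL566.Contig1_All was lower in drought and higher in cold, with 10 reads in the control, 0 in drought and 40 in cold, and Unigene494_All was higher in drought and lower in cold, with 741, 2262 and 265 reads. At 72 h there were 48, of which 11 were higher in drought and lower in cold and 37 the reverse. The number that independent lists would give in opposite directions was not computed, so these counts have no reference value. CL8238.Contig1_All is among the 11, with 183 reads in the control, 1018 in drought and 16 in cold.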

How the results depend on the processing

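The 2 alternatives named as added were chosen after seeing the data. The 3 other scalings, the minimum of 10 reads and totals without the 100 most abundant unigenes (added after seeing the data) left the 15 counts below at 0.872 to 1.04 times their value. All 28 differences of the unigenes chosen by the rule kept their direction and stayed past the bound under these settings and those below, except that the minimum of 500 bases removes the 12 of shorter unigenes. These 28 were chosen for the firmest bounds in the same data, the weakest being 8.38-fold. Their passing was thus largely set by the choice and is no check of the rule. The other settings moved counts, by construction where they change the bound, the error or the unigenes and reads used. Counts are given for drought 1, 24 and 72 h and cold 1 and 72 h against the control, cold against drought at 1 and 72 h, then the steps drought 24 against 1 h, 72 against 24 h, 72 against 1 h and cold 72 against 1 h, then the unigenes shared by the 3 drought times, by both cold times, by both stresses at 1 h and by both at 72 h, in that order. The stricter confidence level gave 105, 360, 223, 112, 1889, 115 and 2040, then 184, 73, 171 and 1791, then 36, 45, 27 and 74. An interval beyond 1 with a ratio of at least 2 gave 2654, 4343, 3319, 2952, 11060, 2656 and 11077, then 3022, 1991, 2752 and 11336, then 587, 1014, 738 and 1125. An interval beyond 4-fold gave 37, 129, 80, 32, 1072, 32 and 1265, then 64, 44, 62 and 1059, then 10, 11, 7 and 18. An assumed coefficient of variation of 0.2 gave 102, 368, 224, 109, 2101, 102 and 2334, then 174, 83, 176 and 2088, then 28, 32, 21 and 56. One of 0.4 gave 30, 120, 70, 26, 1052, 28 and 1228, then 54, 31, 49 and 1036, then 10, 8, 8 and 15. The ratio of RPKM + 1 gave 3733, 5317, 4181, 3890, 11635, 3889 and 11643, then 4248, 3098, 3754 and 11894, then 770, 1432, 1075 and 1550. Unigenes of at least 500 bases gave 182, 504, 324, 219, 2075, 167 and 2180, then 274, 109, 276 and 2005, then 52, 77, 40 and 103. Thinning to about 2150015 reads, added after seeing the data, gave 166, 503, 320, 195, 2345, 174 and 2459, then 258, 118, 246 and 2292, then 52, 59, 43 and 96, so depth limits every count. A pseudocount of 0.1 lowered the correlation with the control to 0.847, 0.834, 0.848, 0.851 and 0.750 for the 5 stress libraries, with cold 72 h the lowest, and 2 other settings moved it by at most 0.05. At cold 72 h against the control the share of called unigenes that were higher was 51.2% with library totals, 69.8% with TMM factors, 71.6% with median-of-ratios factors and 65.0% with upper-quartile factors. It was 73.6% beyond 4-fold, but 36.6% for an interval beyond 1, 37.1% for the ratio of RPKM + 1 and 47.6% for unigenes of at least 500 bases, where lower unigenes were in excess. The last 3 settings gave 36.6%, 37.1% and 47.5% for cold against drought at 72 h, and 32.1%, 33.2% and 46.3% for cold 72 against 1 h. Under TMM factors 2997 of its 3733 unigenes were called in the same direction. No paired analysis was possible because each group has 1 library. Leaving out a replicate within a group was not possible for the same reason, and the planned gene lists were not run for want of gene names.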

Other observations

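The tests of depth, scaling, coverage, plants or handling, the shared control, the control lying apart and contig clusters below were chosen after the results were seen. Only the test of cold 1 h was written down before its result, as a test of cold itself, and its explanation was narrowed to a response under way at 1 h after the result was seen. At 72 h of cold the library also lacked many unigenes that the others held. Among unigenes with at least 20 reads in total, 1219 were seen in all 5 other libraries and had 0 reads there, where counting alone gives 150 with library totals and 303 with TMM factors. The same number was 126 to 246 for the other libraries, against 93.2 to 132 by counting with library totals. Conversely, 11 unigenes had at least 20 reads at 72 h of cold and 0 in every other library.

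Abundant unigenes were among those called, and the following were chosen after their values were seen, as the most abundant in their sets. CL1491.Contig1_All (2540 bases) was lower in all 5 stress libraries, with 2423 RPKM in the control, 723, 170 and 646 in drought at 1, 24 and 72 h and 798 and 181 in cold at 1 and 72 h. It was 14.2-fold lower at 24 h of drought (95% interval 13.60 to 14.95) and 13.4-fold lower at 72 h of cold (12.8 to 14.0). Its reads covered 53.1 to 53.8% of its length in every library. Unigene24088_All (1066 bases) was 3.89-fold higher at 1 h of cold (3.76 to 4.02) and 2.39-fold higher at 1 h of drought (2.31 to 2.48). Its level was lowest in the control, at 882 RPKM. It was 2108, 2007 and 1594 RPKM in drought at 1, 24 and 72 h, and 3428 and 1592 in cold at 1 and 72 h. CL4639.Contig1_All (4716 bases) was 5.30-fold higher at 72 h of cold (5.14 to 5.46), at 1272 RPKM against 240 in the control. CL340.Contig2_All (5753 bases), which took the most reads of all, was not called in any comparison with the control, where it held 3.19% of reads, and was called higher at 72 h of cold, with 4.20%, than at 1 h, with 1.65%.

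Cold 72 h differed from the control at 3733 unigenes, against at most 846 for the other stress libraries. Its 4301593 reads were close to the 4300030 of drought 24 h, so the libraries' depths left little for the thinning to test. Thinned to about 2150015 reads it gave 2345, against 166 to 503 for the others. Under TMM factors it gave 3586, against at most 847 for the others. Neither depth nor scaling by totals accounts for the gap. Loss of coverage along transcripts was not decided. In the class of 50 to 100 reads per kilobase the median coverage was 83.1% at 72 h of cold and 82.9% in the lowest other library. The margin was 0.19 points (95% bootstrap interval -0.590 to 1.19). Loss predicted the lowest coverage at 72 h of cold in every class, and it was the lowest in none. A margin clear of 0 in every class was not seen either. The interval lay above 0 in only 1 of 4 such classes, 100 to 200 reads per kilobase (0.15 to 1.53). The prediction made for cold was not met at 1 h, where the gap between the sets higher and lower at 72 h, as cold 1 h minus drought, was -0.14 on the log2 scale against drought 1 h (95% bootstrap interval over unigenes -0.20 to -0.08), 0.04 against drought 24 h (-0.03 to 0.10) and 0.09 against drought 72 h (0.03 to 0.17), while 2 drought libraries differed by up to 0.26. A response to cold after 1 h stays open and, with 1 library per treatment and time, cannot be told apart from a difference between plants or handling that is not cold.

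Drought 1 h and cold 1 h shared 63 unigenes in their comparisons with the control. Cold 1 h shared more with drought 24 h, 80 higher and 75 lower. For the 63, counting error of the shared control alone gave 0.7 in simulation, so it does not account for them. An assumed coefficient of variation between plants of 0.4 gave 484 and one of 0.2 gave 7.1. The setting of 0.4 also gave 2139 calls per comparison, against 320 and 357 observed here, and the spread of abundant unigenes in these pairs corresponded to 0.126 and 0.141, so a spread of 0.4 in all unigenes is above what these libraries show, and the spread of less abundant unigenes was not measured. Whether the control library itself lies apart was not decided, since with cold 72 h left out it lay apart from the 4 others at 41 unigenes, against 36 for drought 24 h and 30 for drought 1 h. A response common to both stresses, or a control sampled at another time of day, would give the same picture, and that time is not given in the sources used here.

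Contigs of 1 cluster mostly pointed the same way at 72 h of cold. Of the 130 clusters with at least 2 called contigs, 6 held contigs in opposite directions, against 64.6 on average and at least 43 in 10000 shuffles of directions among called contigs. Independent movement is therefore argued against. Reads split between near-identical contigs were not tested. In CL2898, named here for its size after the values were seen, CL2898.Contig2_All went from 338 reads in the control to 3987 and CL2898.Contig1_All from 186 to 42.

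The coverage column held a few large shifts at similar read numbers. Among unigenes with at least 100 reads in both libraries and a ratio within 2-fold, coverage differed from the control by over 20 percentage points at 10, 15, 9, 5 and 13 unigenes in drought 1, 24 and 72 h and cold 1 and 72 h. CL3723.Contig2_All (1212 bases) had the largest shift at 24 h of drought, from 96.8% with 139 reads to 42.1% with 102 reads.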
